A study of Drosophila melanogaster with 2 samples.

How the data were processed

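Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole Drosophila melanogaster embryos that carried a fusion of the transcription factor dimmed (dimm) with enhanced green fluorescent protein (eGFP). The embryos were aged 0 to 24 hours and the protein was pulled down with an antibody to GFP, per the labels. The series has 1 group with 2 biological replicates, which the labels give as separate biological samples. Chromatin was broken by sonication, with a size range of 200 to 800 per the labels. The files used here hold peaks, not reads, so the depth of each library is unknown and no precision could be taken from it. The aligner, the peak caller and the way the peak signal was normalized are not given in the sources used here. No control library of the series was used here, and the labels name only a possible control experiment.

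The authors deposited 8 peak lists on genome build dm6, per the labels. For each replicate there is a long list of ranked candidate regions and a short list of regions that passed a threshold on the irreproducible discovery rate (IDR), a measure of how well the ranks of a region agree between 2 sets of peaks. For the 2 replicates together there are 2 ranked lists and 2 thresholded lists, of which 1 is marked conservative. The value used for each peak is the signal value that the authors deposited. It is the authors' own value, its normalization is not stated, and it was used only to describe, rank or filter peaks within a list. The ranked lists also hold the −log10 of the global IDR that the authors deposited. Every region of each thresholded list had a −log10 IDR of at least 2 (an IDR of at most 0.01) in its ranked list. Of the 142768 candidates in the ranked list behind the conservative list, 1931 reached that value, and 124 of these are not among the 1807 peaks of the conservative list. In that ranked list the first set of input peaks held coordinates of replicate 1's own candidates in 72.0% of rows and of replicate 2's in 0, and the second set held coordinates of replicate 2's in 72.5% and of replicate 1's in 0. The conservative list was therefore taken as the comparison of replicate 1 with replicate 2. Of its peaks, 88.7% had the widest length, 304 bp.

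Genes came from Ensembl release 115 (BDGP6.54) and bases from the Release 6 genome, whose coordinates are those of dm6. As a check of the build, 99.8% of 30618 annotated start codons read ATG in the genome, and no peak ended beyond its chromosome. Peaks on chromosomes 2L, 2R, 3L, 3R, 4, X and Y were kept, 1770 of 1807 in the conservative list. Peaks that overlapped by at least 1 bp within a list were merged and kept the summit with the highest signal. This left 1739 regions in the conservative list, 1176 in replicate 1, 1114 in replicate 2 and 1855 in the list not marked conservative. Coordinates are 1-based.

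The main list for all results but the overlap of the replicates was the conservative list, and each test was repeated on each replicate's own thresholded list. The tests, the gene lists and most alternatives were fixed before the data were examined. Overlap of the replicates needed at least 1 bp and was compared with 1000 circular shifts of replicate 1's regions along each chromosome (two-sided permutation test). Each summit was put in 1 of 7 location classes, in the order promoter (within 500 bp of an annotated transcription start site, TSS), 5' UTR, 3' UTR, coding exon, other exon, intron and intergenic, and compared with 1000 circular shifts, with Benjamini-Hochberg adjustment over the 7 classes. The density on X was compared with that on 2L, 2R, 3L and 3R by an exact binomial test. Intervals of shares are 95% Wilson intervals and cover counting error only. Regions are not replicates, so these p-values describe the lists, and the check across replicates is whether both replicates' own lists gave the same direction.

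Motifs were sought in a 101 bp window at the summit and in a 101 bp window 500 bp to a side drawn with a fixed seed, and compared by an exact two-sided McNemar test over regions. The fixed motifs were the 10 classes of E-box (CANNTG, the site of basic helix-loop-helix factors) and 8 others, with Benjamini-Hochberg adjustment over the 18. All 2080 classes of 6-mers were scanned the same way. Medians of signal were compared by a two-sided permutation test with 100000 resamples. A gene counted as bound when a summit lay in its annotated span or within 1 kb upstream. Each of 13 fixed lists of protein-coding genes was compared with 10000 random lists matched on deciles of span length (two-sided permutation test), with adjustment over the 13 lists. Symbols were matched to the annotation or to synonyms. Gpa2, NTL, KDELR and col had no single match, and symbols of the same gene within a list were counted once. Results were called at an adjusted p under 0.05.

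The 6-mer scan was tested on simulated data made from 1739 shuffled flank windows. With no class planted it called 0 of 2080 classes. Both sides of the simulation came from the same flank windows and so had the same base composition. Real summit windows averaged 33.7% GC against 43.3% in flanks, so calls that come from composition were not tested by it. Of 20 planted classes it recovered 2 when each was put into 2% of windows, 19 at 5% and 20 at 10%. The gene list test was tested on 200 simulated lists of 30 genes drawn in proportion to span length from 13968 protein-coding genes. At an unadjusted p under 0.05 it called 12 of them, against 121 by Fisher's exact test without matching. It called 113 of 200 lists in which bound genes were drawn 2 times as often, and 195 of 200 at 4 times. These lists leaned to long genes and were scored without adjustment. The recovery therefore does not carry over to lists of short genes, to lists of fewer genes or to adjusted p-values.

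Named genes were chosen by a rule: dimm and Phm in every list, the genes at the 15 strongest regions of the conservative list (the gene holding the summit with the nearest TSS, otherwise the nearest TSS), and up to 4 bound members of each fixed list in order of signal, where each replicate's own list also bound them. Genes that share a summit are said to share it. The alternatives fixed beforehand were other promoter sizes, motif windows, flanks and gene assignments, a shuffled background, the list not marked conservative, each replicate alone, the stronger 50% of regions by signal, and peaks left unmerged. A background of candidate regions that did not pass the threshold and the location shares among summits outside promoters (the same shifts, adjusted over 6 classes) were added after the data had been seen, as were all alternatives for the ribosomal protein list taken alone. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 were used.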

Results

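The genome-wide binding of dimm, a basic helix-loop-helix (bHLH) transcription factor known for its role in peptide-secreting neuroendocrine cells, was mapped by ChIP-seq in whole Drosophila melanogaster embryos. The factor carried an eGFP tag and was pulled down with an antibody to GFP. The embryos were 0 to 24 hours old, so the sample mixed all embryonic tissues. The series has 1 group with 2 biological replicates and no second condition. The comparisons its design allows are therefore between the replicates, and between the bound regions and the rest of the genome. The depth of the libraries is unknown. All coordinates are on build dm6.

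The replicates shared most of their bound regions. Replicate 1 had 1176 regions on the main chromosomes and replicate 2 had 1114. Of replicate 1's regions, 819 (69.6%, 95% interval 67.0 to 72.2%) overlapped a region of replicate 2, and these were 73.5% (70.9 to 76.0%) of replicate 2's regions. Circular shifts gave a mean overlap of 0.458% and at most 1.28% (permutation p = 0.001, the smallest that 1000 shifts can give). In the shared regions the summits lay a median of 16 bp apart, and 98.8% lay within 100 bp. The authors' signal values of the 819 shared regions were correlated across regions (Spearman's rho 0.784, and Pearson's r 0.873 on the log2 scale), though regions are not independent replicates.

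**Figure D1:**
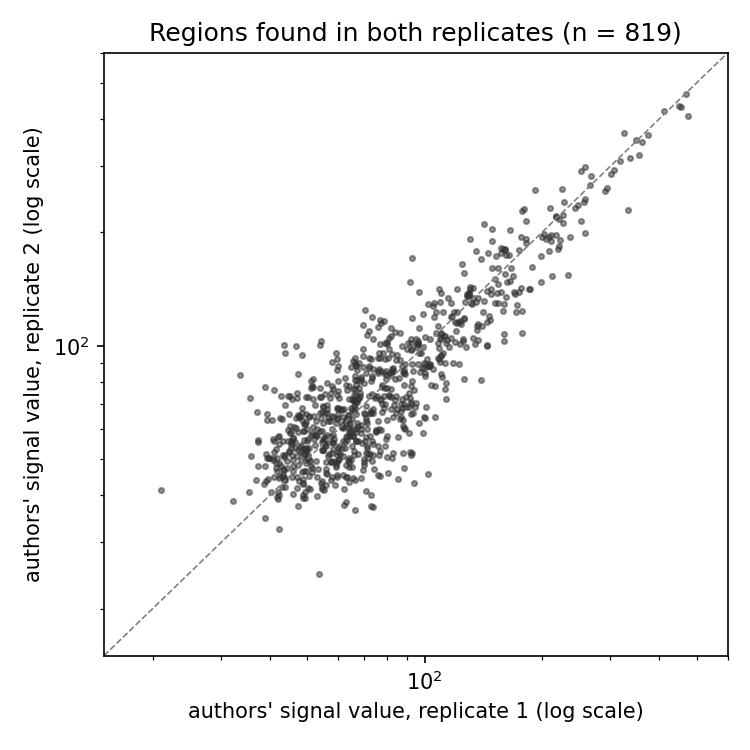
Signal values of the 819 regions found in both replicates' thresholded lists, replicate 1 on the x axis and replicate 2 on the y axis, both on log scales and in the authors' units. Each point is a region and the dashed line marks equal values; the points follow the line, with a Spearman's rho of 0.784.

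The conservative list, which compares both replicates, held 1739 merged regions, and its strongest ones lay mainly at promoters. The strongest had a signal of 925.992 and lay on X from 2703756 to 2704028, between Ugalt, a transporter of UDP-galactose, and eIF2Bbeta, a subunit of a translation initiation factor, with the summit 43 bp from the TSS of Ugalt. Of the 15 strongest regions, 12 had promoter summits, 2 lay in introns and 1 was intergenic, and 9 of the 12 promoter summits lay in the span or upstream kilobase of more than 1 gene. All 15 had a region in each replicate's own list, within the first 15 by signal in replicate 1 and the first 31 in replicate 2. The conservative list was itself made from the agreement of the 2 replicates, so this is no independent check.

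The next regions by signal were those of CG14100 (888, 3L, 19590495 to 19590740, promoter), an intron of CG11050 (887, 2L, 6612596 to 6612863) and the promoter shared by mRpL41, a mitochondrial ribosomal protein gene, and CG8079 (885, 2R, 15217635 to 15217875). The promoter shared by CG7601 and CIA30 had a signal of 813 (3R, 29736739 to 29736985). A region in ph-p, which encodes a Polycomb group protein, had a signal of 740 with its summit 498 bp from a TSS of that gene (X, 2137243 to 2137477). The summit shared by Art3, an arginine methyltransferase gene, and mRpS10, a mitochondrial ribosomal protein gene, had a signal of 699.8. The summit shared by PNPase, an RNA-degrading exonuclease gene, and Gprk2 had a signal of 699.7. An intergenic region 894 bp from the TSS of lncRNA:CR45643 had a signal of 696. Below these came the promoters of Tcs5 (679, shared with CHMP2B), CG18549 (660), CenG1A (629, shared with mRpS23) and Chro, a chromosomal protein gene (603, shared with Ssl1, a subunit of a general transcription factor). The last of the 15 were an intron of HmgZ (601, within the upstream kilobase of HmgD), both genes of HMG-box proteins, and the promoter of CG5611 (560.0, shared with Mtl).

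Over the whole conservative list, promoters held 754 of 1739 summits (43.4%, 95% interval 41.0 to 45.7%). Circular shifts placed 13.5% ± 0.92 (SD over shifts) there, so the share was 3.20 times that of shifted summits (permutation test, adjusted p = 0.00175, from the smallest p that 1000 shifts can give). The promoter share was 48.1% in replicate 1's own list and 49.5% in replicate 2's (48.8% ± 0.942, SD, n = 2), above the shifts in both. Because the classes sum to 100%, this excess alone lowers every other share, so the other classes were also compared among the 985 summits outside promoters, a test chosen after the data had been seen. There, introns held 650 summits (66.0%, interval 63.0 to 68.9%) against 45.7% ± 1.6 for shifts (adjusted permutation p = 0.002), with 66.2% and 69.6% in the replicates' own lists. Coding exons (24 summits, 2.44% against 15.02%) and 3' UTRs (12 summits, 1.22% against 5.84%) held fewer than shifts, each with an adjusted permutation p of 0.002 and called lower in both replicates' own lists. The shares outside promoters also sum to 100%, so these low shares alone raise that of introns. How much of the intron excess comes from this was not tested. Other exons held 17 (1.73% against 0.964%, adjusted permutation p = 0.0135). Intergenic sequence held 272 (27.6% against 31.6%, adjusted permutation p = 0.0456) and was not called in replicate 1's own list. Of all summits, 37.4% lay in introns against 39.5% for shifts, which did not pass (adjusted permutation p = 0.196). That share was lower still in lists with more promoter summits, at 34.4% and 35.2% in the replicates' own lists. Promoter summits lay a median of 143 bp from the nearest TSS.

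**Figure D2:**
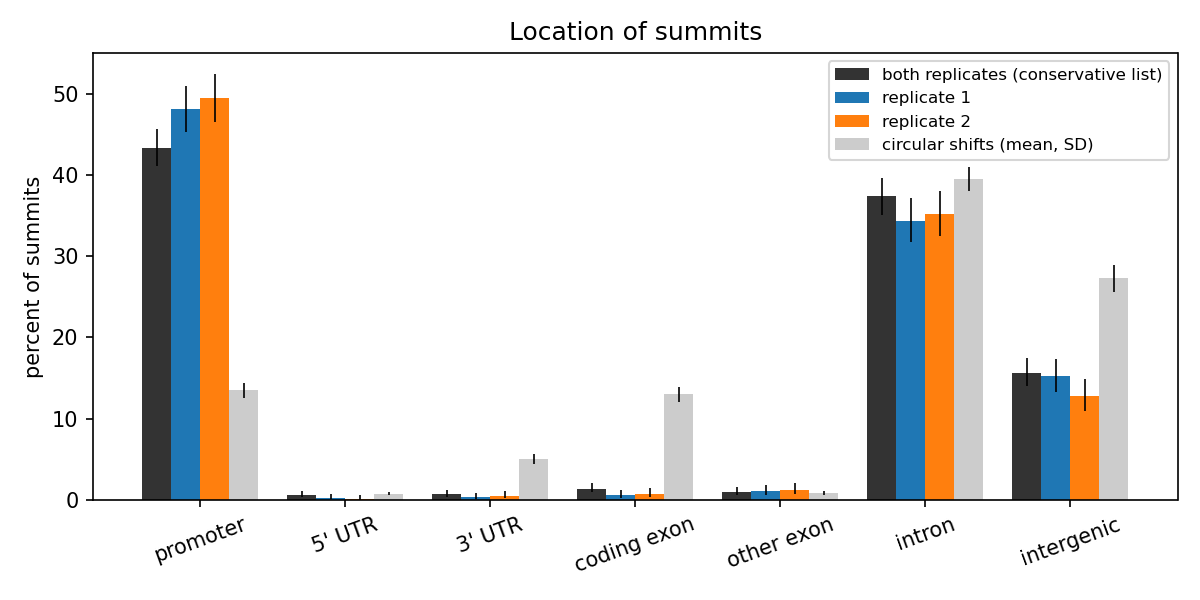
Percent of summits (y axis) in each of 7 location classes (x axis) for the conservative list, for each replicate's own list and for circular shifts of the conservative list. Error bars are 95% Wilson intervals for the lists and the SD over 1000 shifts for the grey bars; promoters held 43.4%, 48.1% and 49.5% of summits against 13.5% for shifts.

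Bound regions were somewhat denser on the X chromosome than on the autosomes. The conservative list had 361 regions on X (15.3 per Mb) and 1375 on 2L, 2R, 3L and 3R (12.6 per Mb), a ratio of 1.22 (exact binomial p = 0.00121). The ratio was 1.19 in replicate 2's own list (exact p = 0.0229) and 1.13 in replicate 1's, where it did not pass (exact p = 0.10). The binomial test takes regions as independent draws, but regions cluster, with 12 in kirre on X alone. These p-values may therefore be too small. Chromosome Y held 3 regions and chromosome 4 held 0, where the autosomal density would give 17.01. A further 3 regions on chromosome 4 passed the IDR threshold but are not in the conservative list. Replicate 1's own list had 1 region on chromosome 4. Candidate regions were also sparse on chromosome 4, at 58.6 per Mb against 874 per Mb on the autosome arms.

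The question behind this assay is which genes the peptidergic factor dimm binds, and the lists of neuropeptide production passed no test against length-matched random lists. dimm itself (FBgn0023091, 2L, 21331756 to 21342155) had no region in any thresholded list, and neither had Phm (FBgn0283509, 2R, 23985175 to 23988455), which encodes an enzyme that amidates neuropeptides. Their strongest candidates in the ranked list of both replicates had signals of 40.2 (dimm) and 39.5 (Phm), ranks 6732 and 7303 of 139701 candidates. The conservative list had a median of 90.6 and a lowest value of 24.3. A signal of 47.0 would already rank 1738 against its 1739 merged regions, so both candidates were weaker than nearly all listed regions. Candidates of any strength were missing from 103 kb next to dimm (2L, 21229345 to 21332651), an interval that ends near the 5' end of the gene, and the rest of dimm held candidates. The fixed list for processing and releasing neuropeptides is broad and also holds VMAT, a vesicular monoamine transporter gene. Of its 22 genes, 4 were bound (18.2%) against 20.7% ± 8.33 (SD) in length-matched random lists (permutation test, adjusted p = 0.945). Counting only summits within 500 bp of a TSS, the same 18.2% stood against 9.18% (adjusted permutation p = 0.563), so the direction depended on the rule. Of 47 neuropeptide genes 4 were bound (8.51%, against 9.39% ± 4.06, adjusted permutation p = 1). The Wilson interval of the share was 7.31 to 38.5% for the processing list and 3.36 to 19.9% for the neuropeptide list. Both intervals reach well above the means of random lists, so a raised share in either list stays open. The sample mixed all embryonic tissues, so a missing region at Phm or a listed gene does not show that the gene is unbound.

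Single genes of peptide production were bound in both replicates. The share of the processing list was not above random lists, at 13.6% in each replicate's own list against 15.1% (replicate 1) and 15.2% (replicate 2). No control was used here, so whether these regions depend on dimm was not tested. The promoter of amon, which encodes a prohormone convertase, had a signal of 255 (3R, 26714314 to 26714464), and 127 and 131 in the replicates' own lists. Pal1, an enzyme gene of peptide amidation, had a promoter region of 287 (2R, 9959759 to 9960062, shared with Pdrg1). Fur1, a furin-type convertase gene, had one of 171 (3R, 25473131 to 25473434, shared with Vps33B). The fourth bound member, Rab3, was not bound in both replicates' own lists. Among neuropeptide genes, an intron of ITP, the ion transport peptide gene, had a region of 197 (2R, 24539267 to 24539570, shared with CG4622), and amn had one of 105 (X, 19889454 to 19889757, shared with Hers). Nplp2 and Dh31 were bound in the conservative list but not in both replicates' own lists, and each replicate alone bound 2 of the 47 (4.26%), as did the stronger 50% of regions. Rab3, Nplp2 and Dh31 were picked for naming after their values had been seen.

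The related lists of secretory genes, peptidergic cell fate regulators and bHLH factors passed no test against length-matched random lists. Of 23 genes of the secretory pathway and its stress response 4 were bound (17.4% against 12.1%, adjusted permutation p = 0.8125), and in replicate 1's own list 5 were (21.7% against 9.06%, permutation p = 0.048, adjusted p = 0.312) and in replicate 2's 3 were (13.04% against 8.37%, adjusted permutation p = 0.767). They included the promoters of TRAM, a translocon component gene (340, shared with CG32815), of Sec61alpha, the channel of the endoplasmic reticulum (122, shared with Daxx and a noncoding RNA), and of Xbp1, a stress response factor (86.2). Of 21 regulators of peptidergic cell fate only grh was bound, in an intron with a signal of 130 (4.76% against 24.7% ± 9.18, permutation p = 0.034, adjusted p = 0.221). Of 49 bHLH genes 10 were bound (20.4% against 14.02% ± 4.71, adjusted permutation p = 0.412), and 3 of them also in both replicates' own lists. These were gce (193, shared with an antisense RNA whose TSS lies nearer), sima, the hypoxia factor gene (140, intron), and E(spl)m3-HLH, a Notch target (94.9, promoter, shared with a noncoding RNA). With circular shifts as background the bHLH list passed (adjusted permutation p = 0.0325), but the replicates lay on opposite sides of random lists, with 3 bound in replicate 1's own list (6.12% against 10.2%) and 8 in replicate 2's (16.3% against 9.98%).

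The cytoplasmic ribosomal protein genes were the 1 fixed list of 13 that was called as bound more often than length-matched random lists. Of 86 such genes 27 were bound (31.4%, 95% interval 22.6 to 41.8%) against 6.56% ± 2.63 (SD) in length-matched random lists, a ratio of 4.78 (permutation p = 0.0001, the smallest that 10000 lists can give; adjusted p = 0.0013). Replicate 1's own list bound 21 (24.4%) and replicate 2's bound 20 (23.3%), each also at an adjusted permutation p of 0.0013, and 15 genes were bound in all 3 lists. The strongest were RpL7 (251, 2L, 10200988 to 10201111, shared with Ripalpha), RpS27 (235, 3R, 25247452 to 25247567, shared with Nup37 and a noncoding RNA), RpL32 (172, 3R, 30046145 to 30046448, shared with CG7943) and RpL14 (165, 3L, 8600808 to 8601111, shared with Nelf-E and 2 small nucleolar RNAs). In the stronger 50% of regions the share was 15.1% (adjusted permutation p = 0.0013). All 28 regions at these genes had promoter summits. Their median signal, 90.3, did not differ by the test from the 108 of other promoter regions (permutation p = 0.24).

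Lists of markers of other embryonic tissues passed no test against random lists. Of 24 pan-neuronal and synaptic genes 4 were bound (adjusted permutation p = 0.8125), among them elav, a neuronal RNA-binding protein gene (220, promoter, shared with arg and a noncoding RNA), and ChAT, the acetylcholine synthesis gene (108, at the TSS of a noncoding RNA inside it). Of 16 glial genes 6 were bound (37.5% against 20.6% ± 9.93, adjusted permutation p = 0.412), and the list passed by Fisher's exact test, which takes no account of gene length. They included moody (245, promoter, shared with CG4313), Gs2, a glutamine synthetase gene (113, intron), and loco (113, intron). Of 25 muscle and mesoderm genes 5 were bound (adjusted permutation p = 1), among them tin, a heart and mesoderm factor (174), sls, a titin-like gene (146), kirre (144) and mbc (114, shared with Nup98-96). Of 16 epidermis genes 2 were bound (adjusted permutation p = 0.945), with grh again the 1 bound in both replicates. Of 18 gut, fat body and blood genes 1 was bound, ush (135, intron; adjusted permutation p = 0.412). Of 14 trachea and salivary gland genes 2 were bound, with rib in both replicates (125, intron; adjusted permutation p = 0.945). Of 35 segmentation and Hox genes 3 were bound (8.57% against 18.4% ± 6.33, adjusted permutation p = 0.412), and 0 of these in both replicates' own lists. Classes of RNA genes and histone genes passed no test, with few summits expected in any of them: 3 summits within 500 bp of a tRNA gene against 2.96 under shifts, 4 near snoRNA genes against 2.26, 1 near snRNA genes against 0.469, 1 near histone genes against 1.72 and 0 near rRNA genes against 0.652 (adjusted permutation p at least 0.95).

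**Figure D3:**
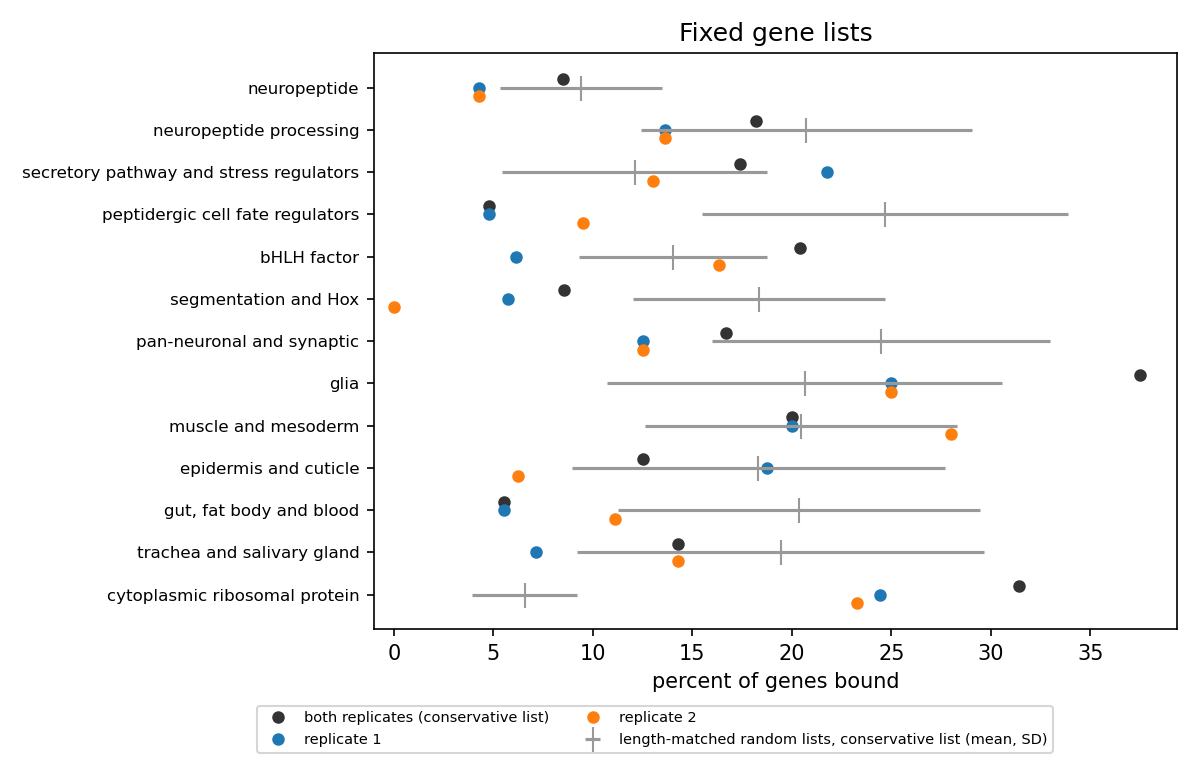
Percent of genes bound (x axis) in each of 13 fixed gene lists (y axis) for the conservative list and each replicate's own list, as points. Grey marks are the mean and SD of 10000 length-matched random lists for the conservative list; the ribosomal protein list lies at 31.4%, 24.4% and 23.3% against 6.56%.

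No E-box class was called more frequent at summits than 500 bp beside them. The class CATATG stood within 50 bp of the summit in 68 regions (3.91%) and in a flank window of the same size in 70 (4.03%), with 68 and 70 regions having it in 1 window alone (ratio 0.971, exact McNemar p = 0.932). In the replicates' own lists the ratio was 1.12 (exact p = 0.672) and 0.878 (exact p = 0.602). With the flank 300 bp away the ratio was 1.56 (exact p = 0.0279), and CATATG was then called higher. It was also above 1 with the flank 1000 bp away (1.28, exact p = 0.223) and against shuffled windows (1.35, exact p = 0.132), without passing. Against candidates with the same GC content the odds ratio was 1.37 (3.91% against 2.88%, Fisher's exact p = 0.111). The share in the main flanks, 4.03%, was above that in each of these other backgrounds (2.53% at 300 bp, 3.11% at 1000 bp, 2.93% in shuffled windows). Of the 10 E-box classes, 0 were higher at summits by the exact McNemar test, at an adjusted or an unadjusted p under 0.05, and 7 were lower, among them CACCTG (2.59% of summits against 5.46% of flanks, adjusted exact p = 1.12e-04), CACGTG (0.518% against 1.67%) and CAGCTG (2.99% against 4.66%). In each replicate's own list 4 classes were lower, but only CACATG and CAGCTG were called lower in both. CACCTG was not called in replicate 1's list (adjusted exact p = 0.0718) and CACGTG not in replicate 2's (adjusted exact p = 0.235). Against shuffled summit windows CAGCTG was instead called higher. Against summits of candidate regions with the same GC content, an alternative chosen after the data had been seen, 0 classes were higher and 0 lower by Fisher's exact test. Of the other fixed motifs, the homeodomain motif TTAATTA (5.92% against 3.80%, adjusted exact p = 0.00881) and the GATA motif AGATAA (7.94% against 5.23%, adjusted exact p = 0.00426) were higher, and GAGAG (8.80% against 15.1%) and CACACA (5.64% against 11.6%) were lower. GAGAG and CACACA were called lower in both replicates' own lists, TTAATTA was called higher in replicate 1's alone, AGATAA in neither, and TTTATG, not called in the main comparison, in replicate 2's alone (14.004% against 10.2%, adjusted exact p = 0.0202). Neither TTAATTA nor AGATAA was called higher against GC-matched candidates, against shuffled windows or in the stronger 50% of regions, and against shuffled windows GAGAG was called higher. TATCGATA stood at 13 summits alone and 4 flanks alone and was not called (adjusted exact p = 0.0736), but it was called higher against shuffled windows, with the flank 1000 bp away, with a wider window and in the list not marked conservative; it was called in neither replicate's own list.

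Summits were rich in A and T. The GC content of the summit window averaged 33.7% against 43.3% in the flank window, and was lower at the summit in 75.1% of regions; the replicates' own lists gave 32.3% and 32.6% at summits. Of all classes of 6-mers, 313 were higher at summits and 657 lower (exact McNemar test, adjusted p under 0.05), and all 36 classes without G or C were among the higher ones. TTAAAA led, in 33.8% of summit windows against 13.6% of flanks (adjusted exact p = 1.52e-40). The replicates' own lists gave 272 and 268 higher classes. Against candidate summits matched on GC content, only 1 class was higher, ACAGTG, in 7.36% of regions against 3.57% of matched candidates (adjusted Fisher's exact p = 0.00205). ACAGTG holds the reverse complement of CACTG. CACTG on either strand was commonest beside the AT-rich core, reaching 11.9% of regions in a 20 bp bin between 40 and 120 bp from the summit, against a mean of 3.96% from 400 to 600 bp.

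**Figure D4:**
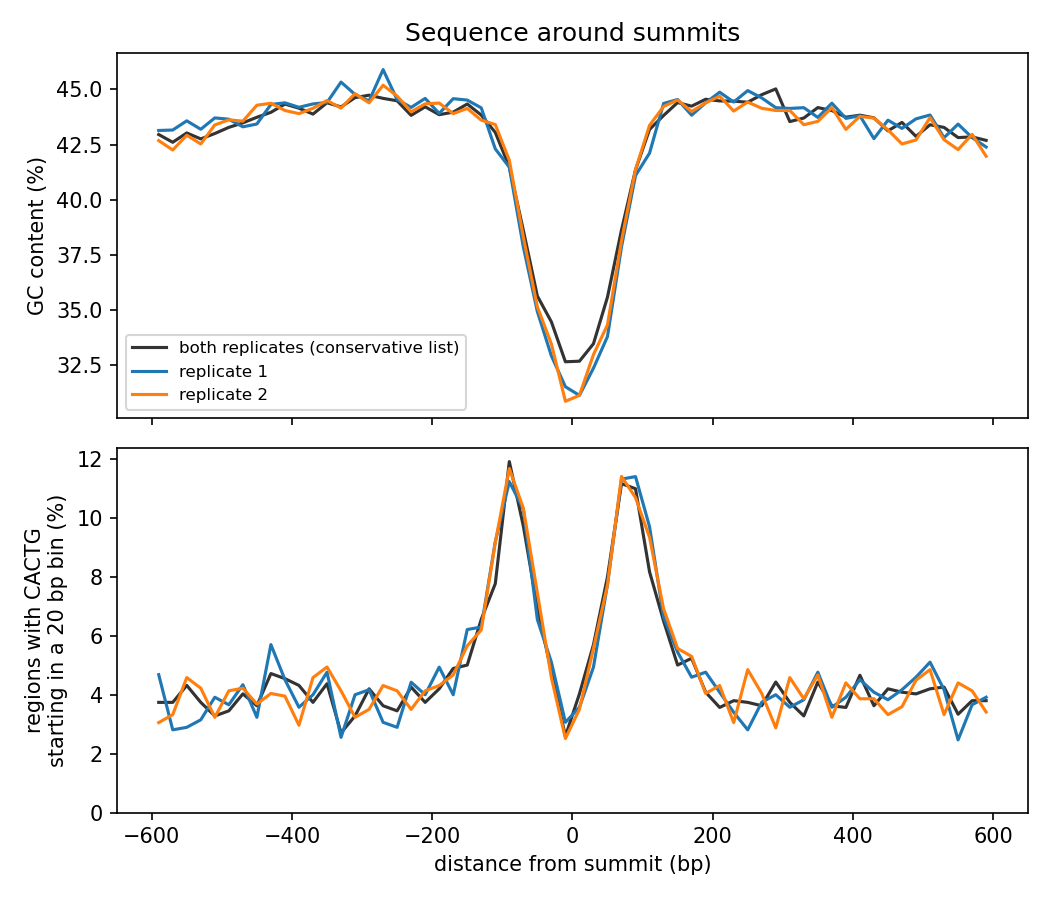
GC content (upper panel, percent) and percent of regions with CACTG on either strand starting in each 20 bp bin (lower panel) against the distance from the summit in bp, for the conservative list and each replicate's own list. GC content falls to 32.7%, 31.1% and 30.9% at the summit, and CACTG rises on both sides of it to 11.9%, 11.4% and 11.7%.

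Promoter regions had a higher signal than the others, and CATATG made no detectable difference. The median signal was 107 in 754 promoter regions and 83.0 in 985 others (difference 24.2, permutation p = 1e-05, the smallest that 100000 resamples can give). The difference was 9.22 in replicate 1's own list and 8.53 in replicate 2's, whose signal values are lower throughout (permutation p = 1e-05 and 2e-05). The 68 regions with CATATG at the summit had a median signal of 97.9 and the 1671 without it 91.3 (permutation p = 0.41). The difference, 6.55, ranged from 1.35 in replicate 2's own list to 17.5 in the stronger 50% of regions and passed in none.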

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

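Sets of peaks lie outside the comparisons above and hold signal. The conservative list had 37 peaks (2.05%) on contigs that belong to X but have no place on it, spread over 35 contigs with at most 2 on any of them. The strongest of them had a signal of 527, and their median was 79.9, against 89.9 for the whole list. Replicate 1's own list had 39 such peaks and replicate 2's had 15. They were left out of all tests, which used the main chromosomes only.

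The ranked list held 124 regions that passed the IDR threshold and were not among the conservative peaks, 78 of them on the main chromosomes and 46 on other contigs. Several were strong: 33 of those on the main chromosomes lay above the median of the conservative list. The strongest, with a signal of 816 (2L, 480967 to 481217), lay in an intron of ush, 1414 bp from the TSS of cbt, and would rank 5 among the conservative regions. It was followed by an intron of Lk6 (677, 3R, 11760929 to 11761168) and the promoter of larp (446, 3R, 28326507 to 28326692). Introns of tara (335) and trx (314) were also among them, as were 2 regions on X whose nearest TSS is that of a 28S rRNA pseudogene (438 and 272). These genes were named after their values were seen. Why they are not listed was not tested.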

How the results depend on the processing

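The overlap of the replicates, the promoter share, both signal comparisons and the shares of the neuropeptide, neuropeptide processing and ribosomal protein lists kept their side of the threshold under every alternative run for them. Of 114 values over all results 1 was weaker, 4 were stronger, 2 were reversed and 6 moved. The overlap ranged from 66.3% to 73.8%, the promoter share from 33.5% to 55.3% and the share of ribosomal protein genes bound from 15.1% (the stronger 50% of regions) to 34.9%. The intron share passed the test with promoters of 1000 bp (29.7%), in the stronger 50% by signal (34.0%) and with each replicate left out in turn (34.4% to 35.2%), all with more promoter summits, which lowers every other share. Among summits outside promoters it turned to above the shifts (66.0%). The X ratio was 1.13 to 1.19 with a replicate left out, and the lower value, without replicate 2, did not pass. CATATG, at 0.971 in the main comparison, was above 1 in most alternatives and passed only with the flank 300 bp away (1.56), where 1 E-box class was called higher (CATATG itself), as was 1 (CAGCTG) against shuffled windows. Against candidates matched on GC content the count of higher 6-mer classes fell to 1. The count of over-represented gene lists rose to 2 with Fisher's exact test (glia added), with circular shifts and with candidate regions as background (bHLH added in both). For the other changes the cause was not tested. The backgrounds of candidates, the share outside promoters and all alternatives for the ribosomal protein list alone were chosen after the data had been seen. No paired analysis was possible because the series has 1 group. The depth of the libraries is unknown, so what it limits could not be tested.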

Other observations

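Genes of mitochondrial ribosomal proteins, which appeared among the strongest regions, were bound in both replicates. Of 73 genes with such a symbol, 10 were bound (13.7%) against 5.01% ± 2.54 (SD) in length-matched random lists (permutation p = 0.003), with 7 in replicate 1's own list (permutation p = 0.017) and 10 in replicate 2's (permutation p = 0.0001, the smallest possible). This list was chosen after the strongest regions had been seen, so it is no independent test. Single long genes held several regions: kirre, which encodes an adhesion protein of founder muscle cells, held 12 and ush held 5.

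All tests in the next paragraphs were chosen only after the patterns had been seen. The clearest pattern in the sequence was a set of 8-mers holding CACTG on either side of the AT-rich summits. Of 32896 classes of 8-mers compared between 40 to 140 bp and 440 to 540 bp from the summit in the 629 regions on 2L and 2R, 10 were higher near the summit (exact McNemar test, adjusted p under 0.05) and 9 of these held CACTG. All 10 were called again on 3L, 3R and X (1107 regions), which had already been looked at, so this is no independent check. CACAGTGG, for example, was near the summit alone in 86 regions there and far from it alone in 8 (exact p = 1.24e-17), with 69 against 8 in replicate 1's own list and 69 against 6 in replicate 2's. CACTGAGA gave 60 against 10 and CACTGTAC 62 against 5.

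Base composition is argued against as the cause: on 3L, 3R and X, 32.2% of regions had 1 of the 9 within 150 bp, against 9.58% of candidates with the same GC content (odds ratio 4.47, 95% interval 3.52 to 5.73). Nearness to an annotated promoter is argued against as the only source, since regions over 500 bp from any TSS had them more often than matched candidates (35.9% against 9.20%, odds ratio 5.51, interval 4.01 to 7.68). These candidates had not passed the threshold and were matched on GC content only. An element of open or active sites in general therefore stays open. CACTG as such was not mainly read towards the summit. It was so read on 45.0% of the sides with a copy (interval 39.99 to 50.1%). In the replicates' own lists it was 43.5% (37.6 to 49.5%) and 38.3% (32.7 to 44.3%), which lean away from the summit. A side with copies in both directions counted once for each direction. In a further test, chosen after that result, the 9 were pooled on 3L, 3R and X. They kept the direction commoner for each on 2L and 2R in 87.7% of copies. CACAGTGG alone kept it in 89 of 100, and CAGTGCAC was lowest at 64.4%. The 8-mers overlap, so pooled copies are not independent. Of 58 regions with copies on both sides and a single direction on each side, 51 had them facing opposite ways (exact binomial p = 2.4e-09). Regions with copies in both directions on a side were left out of this count. These 58 are few of the 356 regions with a copy within 150 bp and of the 1107 tested, and most regions held no copy. Some sites may thus hold an element with mirrored arms that is not an E-box, which is a hypothesis from these data; the design names no second group, so no biological explanation was tested, and a pull-down of another tagged factor with the same antibody would show whether these sites depend on dimm.

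The ribosomal protein genes form the second pattern. Of these genes 31.4% were bound and the interval ended at 41.8%, so the signal was not at every member, but transcription was not measured here and a graded effect of it stays open. Close neighbours are argued against as the only source: 15.3% of all protein-coding genes with another gene's TSS within 1 kb were bound, below the 34.5% (interval 23.4 to 47.7%) of the ribosomal protein genes with such a neighbour. Such a neighbour stood beside 19 of the 27 bound members and 55 of all 86. This comparison was not matched on span length or transcription, so a part played by neighbours stays open. The CACTG 8-mers stood within 500 bp of a TSS in 8 of 27 bound and 18 of 59 unbound members (odds ratio 0.96, interval 0.305 to 2.84), too few to tell from other genes (2.13, 1.90 to 2.38). No biological explanation was tested.

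The third pattern is the interval without candidates beside dimm, which was 103 kb long in replicate 1 and 94.1 kb in replicate 2 and took in Hr39, Mondo and crc, a stress factor gene of the fixed secretory list. At the mean density of the arm such an interval would hold 109 candidates of the ranked list of both replicates. In the own ranked lists of replicates 1 and 2 it would hold 84.8 and 83.3. Finding none argues against candidates spaced independently at that density, although the interval was picked because it was empty. Uneven spacing along the arms stays open: intervals as long made up 0.542% of the 5 main arms, this one among them. Repeated sequence cannot be told apart from other sources: 21.9% of the interval was masked as repeats, above the median of 16.9% for such intervals and below their 95th percentile of 41.2%. Extra copies of this stretch from the tagged construct, and the control, stay untested for this interval and for the sparse candidates on chromosome 4, because reads and controls were not analysed here, so no called region at dimm or crc does not show that they are unbound.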
